A study of Mus musculus with 4 samples.

How the data were processed

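The 4 libraries came from mice on a high-fat diet, 1 for each of brown adipose tissue (BAT) sham, BAT surgery, beige adipose tissue (BeAT) sham and BeAT surgery, as labelled. The molecule is given as nuclear RNA, although the protocol in the labels describes minced and digested tissue and a suspension of viable cells. Libraries followed a SeekGene protocol according to the labels. The submitters' processing notes name the mouse build mm10 and Seurat 4.4.0 and 4, without saying what Seurat was used for. The aligner and the counting program are not given in the sources used here. The deposited UMI count tables of the authors, 32285 genes by barcode for each library, were the only data used.

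The tables held 10445 (BAT sham), 9946 (BAT surgery), 10417 (BeAT sham) and 5952 (BeAT surgery) barcodes, 36760 in all. Total UMIs were 47525684, 60409801, 35675477 and 23118695. Nuclei were kept with at least 500 UMIs, at least 300 genes and under 10% of UMIs from mitochondrially encoded genes. These filters removed 29, 4, 34 and 3 nuclei, and the UMI filter alone removed 0. Doublets were scored per library with the Scrublet method at an expected rate of 6% and its automatic threshold. Where that marked under 0.5% or over 20% of a library, the highest-scoring 6% were taken. This applied to BeAT sham, where the threshold marked 0. Doublets removed numbered 446 (4.28%), 811 (8.16%), 623 (6.00%) and 647 (10.9%), and 34163 nuclei remained.

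All libraries were clustered together without batch integration. Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 were used. A cluster took a class name from marker genes fixed before the data were seen. The limits of the naming rule were chosen after the clusters had been seen. A marker counted where it was at least 2-fold over the median of all clusters and found in at least 5% of the cluster. The best class by mean log2 marker level needed at least 3 such markers and a mean marker fold of at least 4. A cluster stayed unnamed where more than 2 mitochondrial genes were among its top 10 genes, or where more markers of another class than of its own were. It also stayed unnamed where its median UMIs were under 33% of the median of its libraries with no marker of its class in the top 10. Last, it stayed unnamed where an unrelated class reached 60% of the best score with at least 3 markers and 60% of that class's marker list. Names are given as "-like" because only RNA was measured.

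The marker genes of the 18 classes included the following. Adipocyte: Adipoq, Plin1, Plin4, Cidec, Lipe, Pnpla3, Acsl1, Pde3b, Adrb3, Sik2, Ghr. Adipose progenitor: Pdgfra, Dcn, Lama2, Fbn1, Col1a2, Col3a1, Abca8a, Opcml, Dpp4, Pi16. Mesothelial: Msln, Upk3b, Krt19, Wt1, Muc16, Upk1b, Lrrn4. Endothelial: Pecam1, Cdh5, Flt1, Ptprb, Cyyr1, Mecom, Tek, Emcn, Kdr, Adgrl4. Lymphatic endothelial: Prox1, Mmrn1, Reln, Flt4, Ccl21a. Pericyte: Rgs5, Abcc9, Kcnj8, Notch3, Pdgfrb, Steap4, Cox4i2. Smooth muscle: Myh11, Acta2, Tagln, Cnn1, Lmod1, Actg2. Macrophage: Adgre1, Mrc1, Csf1r, F13a1, Cd163, C1qa, Cd68, Lyz2. Dendritic: Flt3, Zbtb46, Cd209a, Clec9a, Xcr1, Ccr7. T or NK: Skap1, Cd3e, Cd3g, Themis, Bcl11b, Cd247, Trbc2, Klrb1c. B cell: Ms4a1, Cd79a, Cd79b, Pax5, Bank1, Ighm. Plasma cell: Jchain, Mzb1, Igha, Tnfrsf17, Derl3. Mast: Cpa3, Kit, Ms4a2, Mcpt4, Tpsb2, Cma1. Neutrophil: S100a8, S100a9, Csf3r, Retnlg, Mmp9, Cxcr2. Schwann: Cdh19, Mbp, Scn7a, Sox10. Skeletal muscle: Ttn, Ckm, Acta1, Neb, Mybpc1, Trdn, Myh4, Tnnt3. Epithelial: Epcam, Krt8, Krt18, Elf5, Krt5, Cdh1, Esrp1. Erythroid: Hbb-bs, Hbb-bt, Hba-a1, Hba-a2, Alas2.

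Shares are nuclei of a class over kept nuclei of the library, with exact (Clopper-Pearson) 95% intervals. A share of 0 was given the limit that 3 nuclei would set. Ratios to 0 were bounded by putting 3 in place of the 0. Shares were also taken among nuclei outside the lymphoid, plasma cell, muscle and epithelial classes.

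For genes, UMIs of a class were summed per library and divided by the total of that class to give scaled counts (CPM). The ratio of CPM carries an exact conditional binomial interval. A gene was counted higher or lower where both libraries together held at least 50 UMIs, the ratio was at least 2-fold and the interval excluded 1. This is a rule of size, and no test was run. Classes needed at least 50 nuclei in each library. A gene list was summarised by the median log2 ratio of members with at least 20 UMIs, with an interval from 1000 Poisson draws. Members counted as higher or lower at 1.5-fold with an interval that excluded 1. Each median was placed among 10000 random lists matched in 20 bins of expression. Gene spans and coordinates came from GENCODE M21 (GRCm38), which held 32235 of the gene identifiers. The span trend was taken off by subtracting the median log2 ratio of genes in each of 20 bins of span.

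The named genes were set by a rule fixed before the data were seen. In adipocyte-like nuclei the 8 higher and 8 lower genes with the interval bound farthest from 1 were eligible, and 4 and 4 in progenitor-like, endothelial-like and macrophage-like nuclei. Left out of this ranking were mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked genes, gene models without a name, markers of other classes, and genes below 25% of their highest level in any class of the same library. In each list the 4 members farthest from 0 were eligible. Ucp1, Lep, Adipoq, Ppargc1a and Fasn were always included. Not every member of a list or ranking is named in the text, although all entered the counts and medians. Zic1, Gpx5 and the position genes were added after the values were seen.

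The 26 gene lists included the following members. Thermogenesis: Ucp1, Ppargc1a, Prdm16, Cidea, Dio2, Elovl3, Cox7a1, Cox8b, Kcnk3, Esrrg, Ebf2, Adrb3, Ppara, Zic1, Letmd1, Pank1, Gk. Creatine and calcium cycling: Ckb, Alpl, Gatm, Gamt, Slc6a8, Ryr2, Atp2a2, Atp2a1, Itpr1. Lipogenesis: Fasn, Acaca, Acacb, Acly, Scd1, Scd2, Elovl6, Srebf1, Mlxipl, Me1, Thrsp, Dgat1, Dgat2, Gpam. Lipolysis: Pnpla2, Lipe, Mgll, Abhd5, Plin1, Adrb3, G0s2, Pde3b, Fabp4. Fatty acid oxidation: Cpt1a, Cpt1b, Cpt2, Acadm, Acadl, Acadvl, Hadha, Hadhb, Etfdh, Acaa2, Slc25a20. Fatty acid uptake: Cd36, Lpl, Slc27a1, Slc27a2, Angptl4, Vldlr, Lrp1. Insulin and glucose: Slc2a4, Insr, Irs1, Irs2, Pik3r1, Akt2, Foxo1, Pck1, Hk2, Tbc1d4. Adipokines: Lep, Adipoq, Retn, Cfd, Rbp4, Nrg4, Fgf21, Bmp8b, Apln, Nampt. Respiratory chain: Ndufs1, Ndufa4, Ndufv1, Sdha, Sdhb, Uqcrc1, Uqcrc2, Cox4i1, Cox5a, Cox5b, Atp5a1, Atp5b, Cycs, Cs, Idh3a. Mitochondrially encoded: mt-Nd1, mt-Nd2, mt-Nd3, mt-Nd4, mt-Nd4l, mt-Nd5, mt-Nd6, mt-Co1, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Cytb. Extracellular matrix: Col1a1, Col1a2, Col3a1, Col4a1, Col4a2, Col5a1, Col5a2, Col6a1, Col6a2, Col6a3, Fn1, Lox, Postn, Sparc, Timp1, Mmp2, Mmp14, Ccn2. Inflammation: Tnf, Il6, Il1b, Ccl2, Ccl3, Ccl4, Ccl5, Ccl7, Cxcl1, Cxcl10, Nfkbia, Nlrp3, Tlr2, Tlr4, Saa3. Interferon response: Isg15, Ifit1, Ifit2, Ifit3, Irf7, Stat2, Oasl2, Gbp2, Gbp3, Rsad2, Ifi44, Xaf1. Lipid-associated macrophage: Trem2, Cd9, Spp1, Gpnmb, Lpl, Cd36, Fabp5, Ctsd, Lgals3, Itgax, Plin2, Atp6v0d2, Mmp12. Tissue-resident macrophage: Lyve1, Cd163, Mrc1, F13a1, Cbr2, Timd4, Folr2, Gas6, Selenop, Klf4, Rbpj. Angiogenesis: Vegfa, Kdr, Flt1, Angpt1, Angpt2, Tek, Pdgfb, Aplnr, Hif1a, Efnb2, Dll4, Notch1. Early progenitor: Dpp4, Pi16, Cd55, Anxa3, Wnt2, Sema3c, Dact2, Creb5. Committed preadipocyte: Icam1, Pparg, Fabp4, Cd36, Bmper, F3, Cebpa, Zfp423, Ebf2, Lpl. Endothelial lipid handling: Gpihbp1, Cd36, Fabp4, Fabp5, Lpl, Meox2, Tcf15, Pparg, Rgcc. Circadian clock: Arntl, Clock, Npas2, Per1, Per2, Per3, Cry1, Cry2, Nr1d1, Nr1d2, Dbp, Tef, Ciart. Immediate early and heat shock: Fos, Fosb, Jun, Junb, Jund, Egr1, Atf3, Ier2, Zfp36, Hspa1a, Hspa1b, Hsp90aa1, Dnajb1. Unfolded protein response: Hspa5, Ddit3, Atf4, Xbp1, Herpud1, Dnajb9, Hsp90b1, Trib3. Hypoxia: Slc2a1, Pdk1, Ldha, Bnip3, Egln3, Ankrd37, Car9, Adm, Vegfa, Pfkfb3. Gut hormone and bile acid receptors: Gpbar1, Klb, Fgfr1, Nr1h4, Gipr, Glp1r, Sctr, Insr. Cell cycle: Mki67, Top2a, Kif11, Cenpf, Ccnb1, Cdk1, Aurkb, Pcna, Mcm2, Rrm2. Sex-linked: Xist, Tsix, Ddx3y, Uty, Kdm5d, Eif2s3y.

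A further 8 lists were written after the results were seen, many of their genes from values already seen, with members that included the following. Epididymal epithelium: Gpx5, Adam7, Lcn5, Lcn8, Lcn9, Lcn10, Crisp1, Spag11b, Rnase9, Rnase10, Cst8, Cst11, Ros1. Mammary epithelium: Csn2, Csn3, Csn1s1, Wap, Lalba, Ltf, Prlr, Krt14, Krt5, Elf5, Wfdc18. Subcutaneous fat position: Tbx15, Shox2, En1, Sfrp2, Hoxc9, Hoxc10, Hoxa9. Intra-abdominal fat position: Wt1, Tcf21, Gata4, Gata6, Nr2f1, Hoxa5. Lymph node stroma: Ccl19, Ccl21a, Cxcl13, Madcam1, Tnfsf11, Cr2, Bst1, Enpp2. Germinal centre: Rgs13, S1pr2, Mybl1, Gcsam, Bcl6, Nuggc, Fas. Clock, higher: Arntl, Npas2, Clock. Clock, lower: Dbp, Nr1d1, Nr1d2, Ciart, Tef, Per3. They were read at a level of 50 CPM or, for the lymph node stroma and germinal centre lists, at 4-fold over progenitor-like or B cell-like nuclei.

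Alternatives fixed in advance were at least 1000 UMIs per nucleus, doublets kept, Leiden resolution 0.5, genes centred within each library before clustering, nuclei thinned to 1000 UMIs for the ratios or before clustering, shares outside the lymphoid, plasma cell, muscle and epithelial classes, median-of-ratios size factors, markers of other classes left out, mitochondrial and ribosomal genes left out of totals, gene minimums of 200 UMIs or none, and list members with at least 100 UMIs. A set of 4 settings was added after the data were examined: the span trend taken off, BAT sham in place of BeAT sham, adipocyte cluster 1 only, and cluster 16 counted as progenitor-like.

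The gene comparison was tested on simulated Poisson counts around the pooled mean of each pair of libraries. In these counts 200 genes were changed, 100 at 2-fold and 100 at 4-fold. They held no spread between nuclei or animals, no leaked RNA and no span trend. The numbers that follow therefore cover counting error only and are no error rate for the real data. In adipocyte-like nuclei the 4-fold genes recovered numbered 100 for BAT surgery against sham, 99 for BeAT surgery against sham, 100 between sham libraries and 100 between surgery libraries. Of the 2-fold genes, which lie at the threshold, 49, 58, 45 and 49 were recovered. Unchanged genes called numbered 66 of 13074, 44 of 12559, 9 of 14012 and 16 of 9601. In progenitor-like nuclei 74 (BAT) and 89 (BeAT) of the 4-fold genes were recovered, with 162 of 9698 and 52 of 7808 unchanged genes called. In endothelial-like nuclei the numbers were 93 and 95, with 75 of 7951 and 99 of 7148 called. In macrophage-like nuclei they were 99 and 100, with 13 of 9768 and 24 of 7057 called.

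Software was Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and Matplotlib 3.10.9.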

Results

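Single-nucleus libraries of mouse fat were compared between high-fat-diet mice labelled as a surgery group and as a sham group. The labels gave brown adipose tissue (BAT) and beige adipose tissue (BeAT), with 1 library for each of the 4 groups. No group had a replicate, so no difference was tested against the spread between animals. Every interval given (95%) covers counting error only, except the interval on Pearson r. A ratio given as "at least" puts 3 counts in place of the 0 of 1 library and is no 95% bound. After filters and doublet removal, 9970 nuclei were kept for BAT sham, 9131 for BAT surgery, 9760 for BeAT sham and 5302 for BeAT surgery. Depth differed, with median UMIs of 3978, 5168, 3062.5 and 2647 per kept nucleus in that order. Clustering gave 45 clusters, of which 10 stayed unnamed. The unnamed clusters held 13.8%, 14.8%, 23.0% and 11.6% of nuclei.

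The brown label was not borne out by the genes that define brown fat. Ucp1, which encodes the uncoupling protein of brown and beige adipocytes, gave 2 UMIs in adipocyte-like nuclei of the library labelled BAT sham, 0 in BAT surgery, 3 in BeAT sham and 0 in BeAT surgery. The limit set by 3 UMIs was 0.821 CPM (UMIs scaled to the class total) for BAT surgery and 0.692 for BeAT surgery. Zic1, a gene of classical brown fat that was looked up after the values were seen, gave 1, 0, 0 and 0 UMIs. Cidea, a lipid droplet gene of thermogenic fat, stood at 30.1 CPM in BAT sham and 61.0 in BeAT sham, the reverse of the order the labels imply. The tissue labels are therefore written as labels throughout, and each direction below is a difference between the libraries so labelled. On the mm10 assembly these genes were Ucp1 (chromosome 8, 83290352 to 83298452, plus strand), Zic1 (chromosome 9, 91358058 to 91365810, minus strand), Adipoq (chromosome 16, 23146536 to 23158028, plus strand) and Lep (chromosome 6, 29060220 to 29073877, plus strand).

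In adipocyte-like nuclei the library labelled BAT sham and the library labelled BeAT sham were close: of 13982 genes, 240 were at least 2-fold higher in BAT sham and 154 lower, 2.82% in all. The split depended on scaling, with 195 higher and 190 lower under median-of-ratios size factors, and 81 and 141 after thinning to 1000 UMIs. Higher in BAT sham were Tmem169 (4.13-fold, 2.93 to 5.96), Mageb18 (2.99-fold, 2.84 to 3.14), Grin1 (3.96-fold, 2.46 to 6.67) and Ptchd4 (2.67-fold, 2.45 to 2.91). Lhx8 (2.65-fold, 2.21 to 3.21) also ranked there, a transcription factor gene used as a brown fat marker. Lower were the histone gene Hist1h3f (10.5-fold, 7.85 to 14.3), the immediate early gene Ier2 (3.60-fold, 3.38 to 3.85), Cox8b (3.07-fold, 2.46 to 3.85) and Gpx3 (2.70-fold, 2.49 to 2.93). Thermogenesis genes had a median log2 ratio of −0.21 (−0.28 to −0.12), with 0 higher and 5 lower of 14 genes, and the lower genes included Cidea (2.03-fold, 1.85 to 2.22) and Cox7a1 (3.29-fold, 1.85 to 6.12). Ppargc1a (ratio 0.978, 0.928 to 1.03), the coactivator of mitochondrial biogenesis, was level. Mitochondrially encoded genes had a median of −1.28 (−1.32 to −1.25), with 0 higher and 13 lower of 13 genes, and immediate early and heat shock genes −1.30 (−1.38 to −1.24), with 0 higher and 9 lower of 11 genes. The lipogenesis median was −0.09 (−0.13 to −0.06), with 0 higher and 1 lower of 14 genes, and the clock median 0.01 (−0.10 to 0.05), with 0 higher and 0 lower of 13 genes.

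Adipocyte-like nuclei made up 41.5% (40.5 to 42.5, 4137 nuclei) of the library labelled BAT sham and 6.23% (5.74 to 6.75, 569 nuclei) of the library labelled BAT surgery, 6.66-fold lower (6.10 to 7.28). Epithelial-like nuclei made up most of the latter, at 0.491% (49 nuclei) against 61.6% (60.6 to 62.6, 5627 nuclei), or 125-fold higher (94.7 to 169.7). Adipose progenitor-like nuclei were 15.2% of BAT sham and 0.635% of BAT surgery (1514 and 58 nuclei), 23.9-fold lower (18.4 to 31.6). Unnamed cluster 16, read beside this class further on, held 1.08% and 5.85% and is not in these shares. Counting it as progenitor-like would make the difference much smaller. Endothelial-like nuclei were 4.10-fold lower (3.49 to 4.84). Macrophage-like nuclei held 11.9% and 10.6%, a ratio of 0.891 (0.818 to 0.971). Plasma cell-like nuclei were 11.4-fold higher (5.76 to 25.7), while T or NK cell-like nuclei were slightly fewer (ratio 0.728, 0.584 to 0.906). Schwann-like nuclei numbered 84 and 0 (at least 25.6-fold lower), and skeletal muscle-like nuclei 416 and 0 (at least 127-fold lower).

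The class was not made of the same clusters in the pair. Cluster 1 held 66.7% of adipocyte-like nuclei in BAT sham, whereas cluster 21 held 81.9% of those in BAT surgery. Progenitor-like nuclei of BAT sham lay in clusters 6 (53.9%) and 11 (44.3%), and 91.4% of those in BAT surgery lay in cluster 11. All nuclei of epithelial-like clusters 7, 8, 12, 13, 22, 30, 39 and 45 came from the library labelled BAT surgery, so they cannot be separated from that 1 library. Among nuclei outside the lymphoid, plasma cell, muscle and epithelial classes, adipocyte-like nuclei were 44.8% of BAT sham and 17.5% of BAT surgery, and macrophage-like nuclei 12.9% and 29.9%. Progenitor-like nuclei were 16.4% and 1.79% on that base, and endothelial-like nuclei 8.83% and 5.61%.

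In the library labelled BeAT surgery, lymphoid nuclei outnumbered adipocytes. Adipocyte-like nuclei were 50.5% (49.5 to 51.5, 4926 nuclei) of BeAT sham and 9.37% (8.60 to 10.2, 497 nuclei) of BeAT surgery, 5.38-fold lower (4.91 to 5.92). B cell-like nuclei were 0.410% and 31.2% (29.97 to 32.5, 1655 nuclei), 76.2-fold higher (55.7 to 107). T or NK cell-like nuclei were 1.94% and 29.4% (28.2 to 30.7, 1560 nuclei), 15.2-fold higher (13.1 to 17.8). Dendritic-like (7.25-fold, 5.68 to 9.34), lymphatic endothelial-like (11.3-fold, 6.26 to 22.2) and plasma cell-like nuclei (25 against 2 nuclei, ratio 23.0, 5.74 to 200.4) were also more frequent. Progenitor-like nuclei were 3.65-fold lower (3.03 to 4.42) and endothelial-like nuclei 3.41-fold lower (2.79 to 4.19). Macrophage-like nuclei held 6.28% and 4.94%, a ratio of 0.787 (0.678 to 0.911). Schwann-like nuclei numbered 65 and 2 (ratio 0.0566, 0.00672 to 0.213), and skeletal muscle-like nuclei 0 and 36 (at least 22.1-fold higher).

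Adipocyte-like nuclei of BeAT sham lay in clusters 2 (41.4%), 1 (37.9%) and 9 (20.7%), and those of BeAT surgery in clusters 1 (75.7%) and 21 (13.3%). Progenitor-like nuclei lay mostly in cluster 6 in BeAT sham (76.6%) and cluster 11 in BeAT surgery (60.3%). Outside the lymphoid, plasma cell, muscle and epithelial classes, adipocyte-like nuclei were 51.7% of BeAT sham and 24.5% of BeAT surgery. On that base macrophage-like nuclei were 6.43% and 12.9%, so the direction of their share depended on the base. Progenitor-like nuclei were 9.23% and 6.47%, and endothelial-like nuclei 7.44% and 5.58%, smaller differences than over all nuclei. No nuclei were named mesothelial, pericyte, smooth muscle, mast, neutrophil or erythroid in any library.

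**Figure D1:**
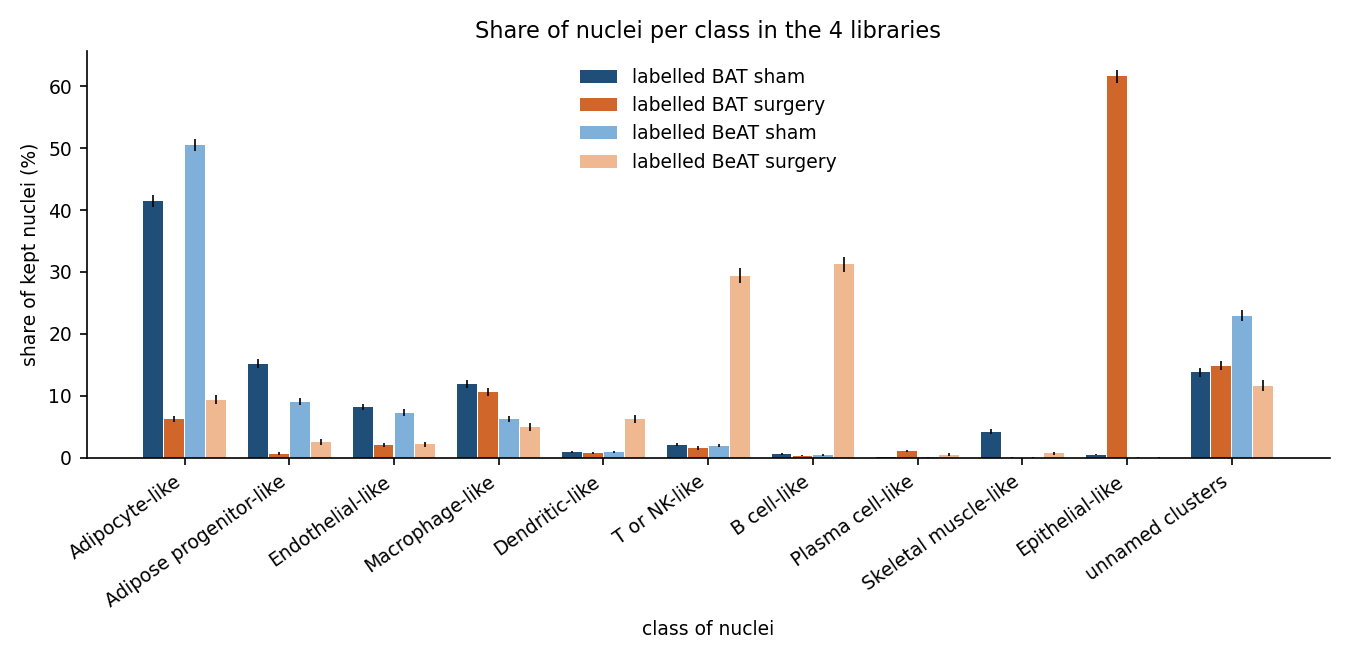
Share of kept nuclei in each class for the 4 libraries, named by their labels. Bars give 95% intervals for counting error within a library.

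RNA from adipocytes reached other droplets in the sham libraries far more than in the surgery libraries. Adipoq, the adiponectin gene, stood in endothelial-like nuclei at 517 CPM in BAT sham, 43.6 in BAT surgery, 664 in BeAT sham and 41.6 in BeAT surgery. In macrophage-like nuclei it stood at 122, 10.1, 149 and 16.8 CPM. The reverse leak ran in the library labelled BAT surgery, where Gpx5, an epididymal glutathione peroxidase gene looked up after the values were seen, reached 1914 CPM in progenitor-like, 2656 in endothelial-like, 1099 in macrophage-like and 597 in adipocyte-like nuclei. No Gpx5 UMI was found outside the epithelial-like class in BAT sham (limit 0.0674 CPM). Lower fat genes outside adipocytes, and higher epididymal genes, are to be read beside these levels. Leaked epithelial RNA also takes a part of each class total in BAT surgery, which lowers the CPM of the class's own genes there. That part was not taken off the ratios. Leak of lymphoid RNA in the library labelled BeAT surgery was not weighed.

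Ratios also followed the genomic span of a gene. In adipocyte-like nuclei the Spearman correlation of log2 ratio with span was 0.341 for BAT and 0.573 for BeAT surgery against sham. In BAT the median log2 ratio was −0.76 for genes up to 2.75 kb and 0.19 for genes from 235 kb, and in BeAT −1.38 and 0.50. Some medians are also given with this trend taken off. Pairs of UMI counts give the surgery library first. The median log2 ratio of all genes lay more than 0.1 from 0 only in endothelial-like nuclei, at 0.105 for BeAT surgery against sham and 0.135 between the sham libraries.

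Adipocyte-like nuclei of the library labelled BAT surgery had higher fatty acid synthesis genes and lower thermogenic and mitochondrially encoded genes than BAT sham. The cytosolic enzymes that make acetyl-CoA and malonyl-CoA had genes among the higher set, Acly (4.83-fold, 4.59 to 5.09) and Acaca (4.72-fold, 4.64 to 4.79). Klb (6.44-fold, 5.64 to 7.34), the co-receptor of FGF21, and Arntl (13.5-fold, 10.7 to 17.1), a core activator of the clock, were also higher. Prdm16 (6.77-fold, 5.71 to 8.10), a regulator of beige and brown identity, was lower, as were the adipokine genes Lep (2.89-fold, 2.67 to 3.14) and Adipoq (1.80-fold, 1.69 to 1.91). Of 13077 genes, 709 were at least 2-fold higher and 1577 lower, or 1396 and 1705 with no minimum of UMIs. Acaca, Pik3r1 and Klb were among the genes that lead cluster 21, in which most of these nuclei lay. Position genes also differed within this pair, as given further on. Surgery and a difference in depot therefore cannot be told apart in these ratios.

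Lipogenesis genes had a median log2 ratio of 0.76 (0.70 to 0.81), with 8 higher and 1 lower of 14 genes. Scd2 (2.94-fold, 2.54 to 3.41) and Fasn (1.64-fold, 1.56 to 1.74) went with Acly and Acaca, while Scd1 (2.80-fold, 2.69 to 2.90), the main fat desaturase gene, went the other way. The thermogenesis median was −0.76 (−0.92 to −0.61), with 2 higher and 8 lower of 12 genes, and its lower genes included Cidea (13.7-fold, 6.93 to 31.9), Ppargc1a (2.34-fold, 2.02 to 2.73) and Cox8b (2.34-fold, 1.099 to 5.95), the last of which was higher when nuclei were thinned to 1000 UMIs. Adipokines stood at −0.79 (−0.86 to −0.74), with 1 higher and 5 lower of 9 genes, but at −0.03 with the span trend taken off. The insulin and glucose median was 0.02 (−0.15 to 0.16), with 4 higher and 3 lower of 11 genes. The regulatory subunit gene Pik3r1 (6.39-fold, 6.24 to 6.55) and Tbc1d4 (3.14-fold, 3.001 to 3.28) were higher. Pck1 (5.21-fold, 4.83 to 5.63) and the glucose transporter gene Slc2a4 (2.49-fold, 2.10 to 2.98) were lower. Gut hormone and bile acid receptor genes had a median of 1.36 (1.26 to 1.46), with 3 higher and 0 lower of 4 genes, from Klb, the secretin receptor gene Sctr (4.17-fold, 3.69 to 4.71) and Fgfr1 (1.58-fold, 1.47 to 1.70). Pnpla2 (2.66-fold, 2.32 to 3.08), the first lipase of triglyceride breakdown, was lower and its activator gene Abhd5 (2.31-fold, 2.11 to 2.53) higher.

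Respiratory chain genes had a median of −0.25 (−0.41 to −0.18), with 1 higher and 2 lower of 16 genes, which became 0.02 with the span trend taken off. Mitochondrially encoded genes kept a lower median, −1.45 (−1.61 to −1.22), with 0 higher and 11 lower of 13 genes, and −0.69 without the trend. The median mitochondrial share of UMIs over all barcodes also differed, at 0.149% in BAT sham, 0.0385% in BAT surgery, 0.454% in BeAT sham and 0.0901% in BeAT surgery, a value that takes in nuclei of every class. Lower mitochondrially encoded genes therefore cannot be told apart from less mitochondrial RNA in the droplets of a whole library. They are not read as a change in adipocytes, here or in the other pairs of libraries. Immediate early and heat shock genes were lower at −1.62 (−1.85 to −1.38), with 0 higher and 9 lower of 10 genes (−0.98 without the trend), including Junb (6.97-fold, 4.73 to 10.7), Jun (5.67-fold, 4.59 to 7.09) and Egr1 (3.84-fold, 2.91 to 5.17). The clock genes split by phase, with the activator gene Arntl higher and the output and repressor genes Dbp (11.8-fold, 8.20 to 17.7), Ciart (11.2-fold, 5.66 to 26.1) and Nr1d1 (4.24-fold, 3.09 to 5.96) lower. The list as a whole stood at −0.46 (−0.74 to −0.27), with 2 higher and 6 lower of 13 genes, which hides these opposite directions. Inflammation genes stood at −1.68 (−1.80 to −0.99), with 1 higher and 5 lower of 8 genes (−0.92 without the trend), and angiogenesis genes at −0.90 (−1.13 to −0.69), with 0 higher and 7 lower of 10 genes.

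Other genes were ranked by single ratio. Higher were Defb25 (215 against 1 UMIs, ratio 1497, 266 to 59402), a defensin gene of the epididymal group and a candidate for leaked RNA, Dnajc6 (47.4-fold, 37.7 to 60.4) and Syt2 (48.6-fold, 36.5 to 65.9). The glucocorticoid-induced chaperone gene Fkbp5 (27.4-fold, 25.7 to 29.2) and the cytokine signalling gene Cish (27.7-fold, 20.3 to 38.5) ranked with them. Masp1 (77.8-fold, 33.9 to 219) and Sez6l (59.9-fold, 31.0 to 129) were also among the higher genes. Lower were the posterior homeobox genes Hoxa9 (2 against 2110 UMIs, ratio 0.00660, 0.000799 to 0.0239), Hoxc10 (0 against 468 UMIs, at least 22.4-fold) and Hoxa10 (0 against 245 UMIs, at least 11.7-fold), then Nnat (18.9-fold, 17.8 to 20.1), St3gal6 (18.7-fold, 13.7 to 26.3) and Fgf14 (15.6-fold, 12.7 to 19.3). Adam3 (29.1-fold, 12.4 to 89.9) and Chrna5 (0 against 254 UMIs, at least 12.2-fold) also ranked among the lower genes.

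The library labelled BeAT surgery also had higher fatty acid synthesis genes than its sham, with lower adipokine and mitochondrial genes. Acly (4.86-fold, 4.63 to 5.10), Acaca (4.84-fold, 4.77 to 4.92) and Acacb (4.28-fold, 4.13 to 4.42) were higher, the last encoding the carboxylase at the mitochondrial membrane. Klb (9.98-fold, 8.78 to 11.4) and Arntl (14.0-fold, 10.4 to 19.02) were higher too. Adipsin and adiponectin genes were lower, Cfd (6.99-fold, 6.71 to 7.28) and Adipoq (2.82-fold, 2.67 to 2.99), with Lep (2.51-fold, 2.35 to 2.69). Of 12549 genes, 568 were at least 2-fold higher and 1907 lower, but 701 and 812 with the span trend taken off, so the excess of lower genes lay mostly in short genes.

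Lipogenesis genes had a median of 0.71 (0.65 to 0.76), with 8 higher and 1 lower of 14 genes, and 0.94 without the trend. Elovl6 (3.43-fold, 3.18 to 3.71) and Fasn (1.67-fold, 1.60 to 1.75) were in the higher set. The thermogenesis median was −0.23 (−0.41 to −0.01), with 1 higher and 4 lower of 14 genes, and it was 0.19 when the library labelled BAT sham stood in for BeAT sham and 0.54 within cluster 1, so no direction is given for the list. Its members included the beta-3 receptor gene Adrb3 (2.22-fold, 2.14 to 2.31), Cidea (1.75-fold, 1.48 to 2.09) and Cox8b (3.14-fold, 1.97 to 5.29) as lower (Cidea was higher in both of those settings), and Ppargc1a (ratio 1.099, 1.004 to 1.202) near level. Insulin and glucose genes were higher at 0.42 (0.35 to 0.48), with 5 higher and 1 lower of 11 genes, with Pik3r1 (6.36-fold, 6.20 to 6.53), Tbc1d4 (2.72-fold, 2.59 to 2.85) and Foxo1 (2.66-fold, 2.54 to 2.78). Gut hormone and bile acid receptor genes stood at 1.49 (1.38 to 1.59), with 3 higher and 0 lower of 4 genes, with Klb, Sctr (4.61-fold, 4.06 to 5.24) and Fgfr1 (1.70-fold, 1.58 to 1.82). Adipokines stood at −0.98 (−1.496 to −0.71), with 1 higher and 5 lower of 9 genes, among them the retinol carrier gene Rbp4 (5.02-fold, 4.33 to 5.84).

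Respiratory chain genes had a median of −0.88 (−0.97 to −0.73), with 1 higher and 10 lower of 16 genes (−0.35 without the trend), with Cox5b (7.98-fold, 5.74 to 11.4) and Cox4i1 (4.91-fold, 4.25 to 5.71). Mitochondrially encoded genes stood at −2.46 (−2.56 to −2.26), with 0 higher and 13 lower of 13 genes (−1.08 without the trend). The limit given for BAT, a lower mitochondrial share over all barcodes, holds here too. Interferon response genes were lower at −1.49 (−2.01 to −1.03), with 0 higher and 9 lower of 13 genes, with Ifit3 (4.58-fold, 2.78 to 8.11) and Isg15 (1 against 82 UMIs, ratio 0.0589, 0.00147 to 0.337), though the latter was higher when nuclei were thinned to 1000 UMIs. Without the trend the median was −0.90. Immediate early and heat shock genes were higher at 0.85 (0.77 to 0.97), with 8 higher and 0 lower of 13 genes (1.66 without the trend), led by Atf3 (11.7-fold, 7.59 to 18.4) and Fosb (5.43-fold, 4.502 to 6.55). Clock genes again split, with Arntl and Clock (2.99-fold, 2.74 to 3.26) higher and Dbp (11.9-fold, 8.65 to 16.7) and Ciart (4.14-fold, 2.81 to 6.33) lower. By single ratio, Cish (49.9-fold, 31.8 to 82.2), Arhgef37 (19.4-fold, 13.7 to 28.2), Osgin1 (15.6-fold, 10.6 to 23.5) and Car2 (14.9-fold, 10.5 to 21.6) led the higher genes. Lsmem1 (14.7-fold, 10.1 to 21.9), Ston1 (13.7-fold, 9.65 to 19.8) and Fkbp5 (12.6-fold, 11.5 to 13.7) followed. Gpx3 (13.8-fold, 9.56 to 20.6), Cavin3 (12.1-fold, 9.17 to 16.3), Gstt3 (0 against 128 UMIs, at least 8.84-fold) and Sncg (8.84-fold, 6.80 to 11.7) led the lower genes, with Flna (8.51-fold, 6.03 to 12.4) and Nnat (6.89-fold, 6.67 to 7.12).

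**Figure D2:**
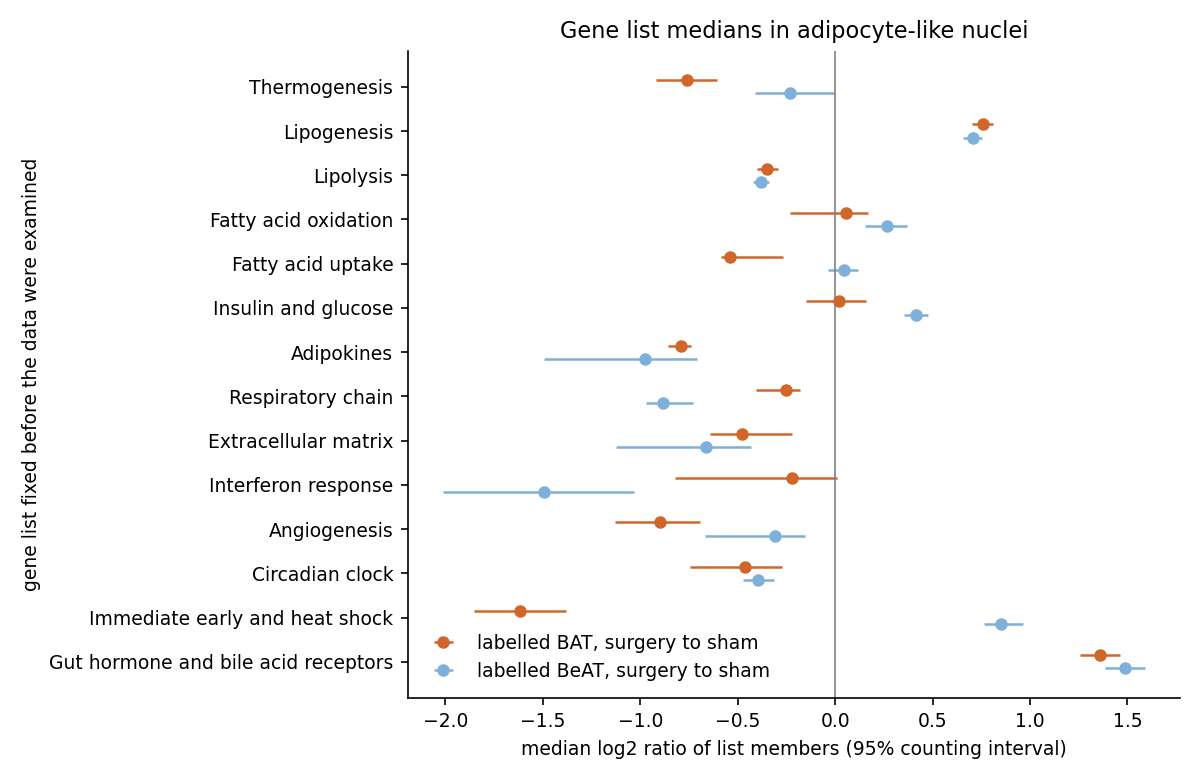
Median log2 ratio of each gene list in adipocyte-like nuclei for each comparison of labelled libraries. Intervals cover counting error only.

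The surgery to sham ratios of the pair of tissue labels went together. Across 12402 genes in adipocyte-like nuclei, Pearson r was 0.581 (0.569 to 0.593) and Spearman rho 0.639, and the ratios shared no library. The interval on r takes each gene as a replicate, which genes are not, so it measures no spread between libraries. Higher in both were 263 genes, where 24.0 would come from independent lists, and lower in both were 694, where 222 would. Opposite calls were rare, with 10 genes higher in BAT and lower in BeAT (82.9 from independent lists) and 24 the other way (64.4). Acly, Acaca, Pik3r1, Klb, Fkbp5, Cish and Arntl were among the genes higher in both, and Nnat, Scd1, Pnpla2, Lep and Dbp among those lower. With the span trend taken off, r was 0.518, with 275 genes higher in both (31.6 from independent lists) and 360 lower in both (73.0).

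**Figure D3:**
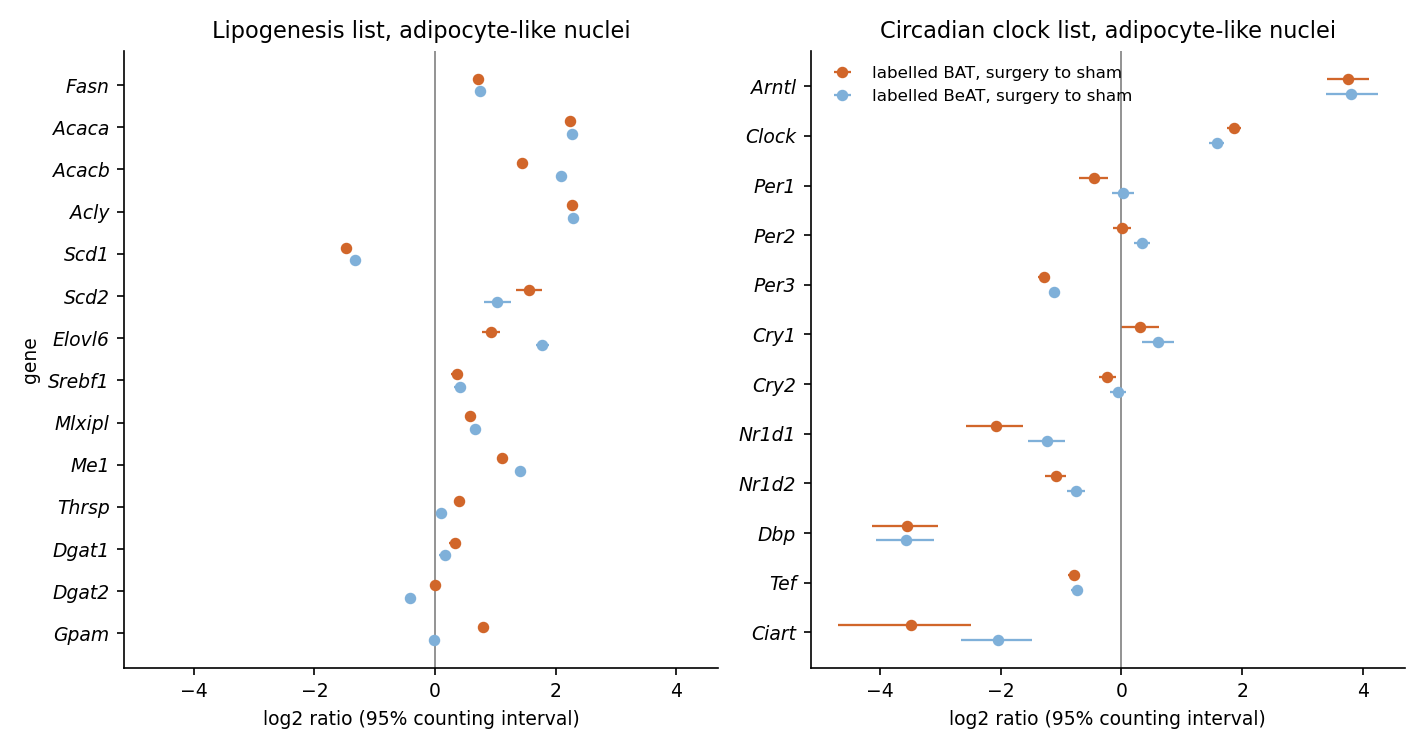
Log2 ratio, surgery to sham, of lipogenesis and clock genes in adipocyte-like nuclei of the libraries labelled BAT and BeAT. Intervals cover counting error only.

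Adipose progenitor-like nuclei of the library labelled BAT surgery (58 nuclei) had lower matrix genes and no UMI of Tbx15, a subcutaneous position gene. Another such gene, Sfrp2, was present (13 against 234 UMIs, ratio 1.57, 0.825 to 2.74). Col1a1 (5.41-fold, 4.06 to 7.36) and Col6a3 (4.999-fold, 3.71 to 6.91) were lower, and the extracellular matrix median was −1.89 (−2.04 to −1.58), with 1 higher and 13 lower of 16 genes. The limb and trunk patterning gene Tbx15 (0 against 2113 UMIs, at least 24.9-fold) was not found. Committed preadipocyte genes stood at −0.91 (−1.60 to −0.78), with 0 higher and 6 lower of 10 genes, with Fabp4 (16.04-fold, 10.3 to 26.6) and the adipogenic regulator gene Pparg (6.25-fold, 3.90 to 10.8). Of 9749 genes, 545 were at least 2-fold higher and 585 lower, but 242 and 469 at a minimum of 200 UMIs and 1007 and 585 with none. Clu (55.2-fold, 31.4 to 99.9), Col6a5 (34.5-fold, 19.1 to 62.6) and Adamts6 (19.7-fold, 13.7 to 28.2) were higher beside Gpx5 (369 against 0 UMIs, at least 3482-fold), the epididymal gene given earlier. Whether leaked epithelial RNA raised any of the first 3, or how far it lowered other genes here, was not tested. Igfbp5 (3 against 4129 UMIs, ratio 0.0206, 0.00424 to 0.0602), Shisa6 (0 against 1093 UMIs, at least 12.9-fold) and Mmp3 (0 against 1083 UMIs, at least 12.8-fold) were lower. Early progenitor genes had a median of 0.18 (0.01 to 0.33), with 3 higher and 3 lower of 8 genes. It was −0.06 without the span trend, −0.81 in nuclei of at least 1000 UMIs and −1.29 with cluster 16 in the class, so no direction is given. Creb5 (2.22-fold, 2.04 to 2.42) was higher but turned round in the last pair of settings.

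In the library labelled BeAT surgery, progenitor-like nuclei (131 nuclei) also had lower matrix genes but more of the early progenitor genes. The matrix median was −1.63 (−1.75 to −1.51), with 0 higher and 13 lower of 16 genes, with Sparc (5.88-fold, 5.25 to 6.61), Col1a1 (5.56-fold, 4.79 to 6.48) and Lum (10.4-fold, 7.20 to 15.8). The early progenitor median was 1.63 (1.505 to 1.79), with 8 higher and 0 lower of 8 genes, with Creb5 (3.65-fold, 3.38 to 3.94), the semaphorin gene Sema3c (3.52-fold, 3.12 to 3.95), the peptidase gene Dpp4 (3.22-fold, 2.79 to 3.72) and Dact2 (3.19-fold, 2.42 to 4.19). Against BAT sham that median was 0.32. BeAT surgery also held more of its progenitor-like nuclei in cluster 11, which Pi16 and Creb5 lead. Committed preadipocyte genes stood at −1.01 (−1.24 to −0.87), with 0 higher and 6 lower of 10 genes, including Fabp4 (11.6-fold, 10.01 to 13.4), a gene that also leaks from adipocytes. Of 7811 genes, 478 were at least 2-fold higher and 1322 lower, or 518 and 661 with the span trend taken off. Tll1 (29.0-fold, 18.2 to 48.5), Dnah3 (18.4-fold, 10.3 to 34.998), Spon1 (9.24-fold, 5.98 to 14.5) and Sntg1 (7.23-fold, 6.35 to 8.23) ranked higher, and Lamc3 (0 against 248 UMIs, at least 17.4-fold), Prune2 (0 against 139 UMIs, at least 9.73-fold) and Cxcl14 (17.5-fold, 7.44 to 54.2) lower.

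Position genes, chosen after the values were seen, were read in progenitor-like nuclei together with clusters 16 and 28. This group differed in make-up, with 1514, 108 and 183 nuclei from these sources in BAT sham and 58, 534 and 3 in BAT surgery. In it Tbx15 stood at 349 CPM in BAT sham and 5.48 in BAT surgery (ratio 0.0157, 0.00809 to 0.0274). It stood at 335 and 353 in BeAT sham and BeAT surgery. Wt1, a gene of visceral mesenchyme, stood at 0 and 326 CPM in the BAT pair (at least 795-fold higher) and at 0 and 32.1 in the BeAT pair. Shox2 (18.7 and 0), En1 (13.3 and 0.457), Hoxc9 (31.3 and 2.28) and Hoxc10 (25.7 and 0) were lower in BAT surgery. Gata6 (2.98-fold, 2.51 to 3.54), Nr2f1 (3.75-fold, 2.41 to 5.86) and Hoxa5 (4.59-fold, 3.52 to 6.01) were higher. In BeAT surgery Hoxc9 (ratio 0.472, 0.238 to 0.855), Hoxc10 (0.142, 0.0382 to 0.373) and Sfrp2 (0.0707, 0.0191 to 0.183) were lower as well, and Wt1 was at least 33.9-fold higher. These made 3 of 7 subcutaneous genes lower and 1 of 4 intra-abdominal genes higher in BeAT. Wt1 is among the genes that lead cluster 16. Without clusters 16 and 28, Shox2 and En1 were too sparse in BAT surgery to be called lower even at 0 UMIs. In progenitor-like nuclei without clusters 16 and 28, 4 of 7 subcutaneous genes were lower and 2 of 4 intra-abdominal genes higher in BAT surgery. In BeAT surgery these were 2 of 7 and 0 of 3, with Hoxc9 no longer counted (ratio 0.572, 0.286 to 1.04), and in adipocyte-like nuclei of BeAT 0 of 6 subcutaneous genes were lower.

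**Figure D4:**
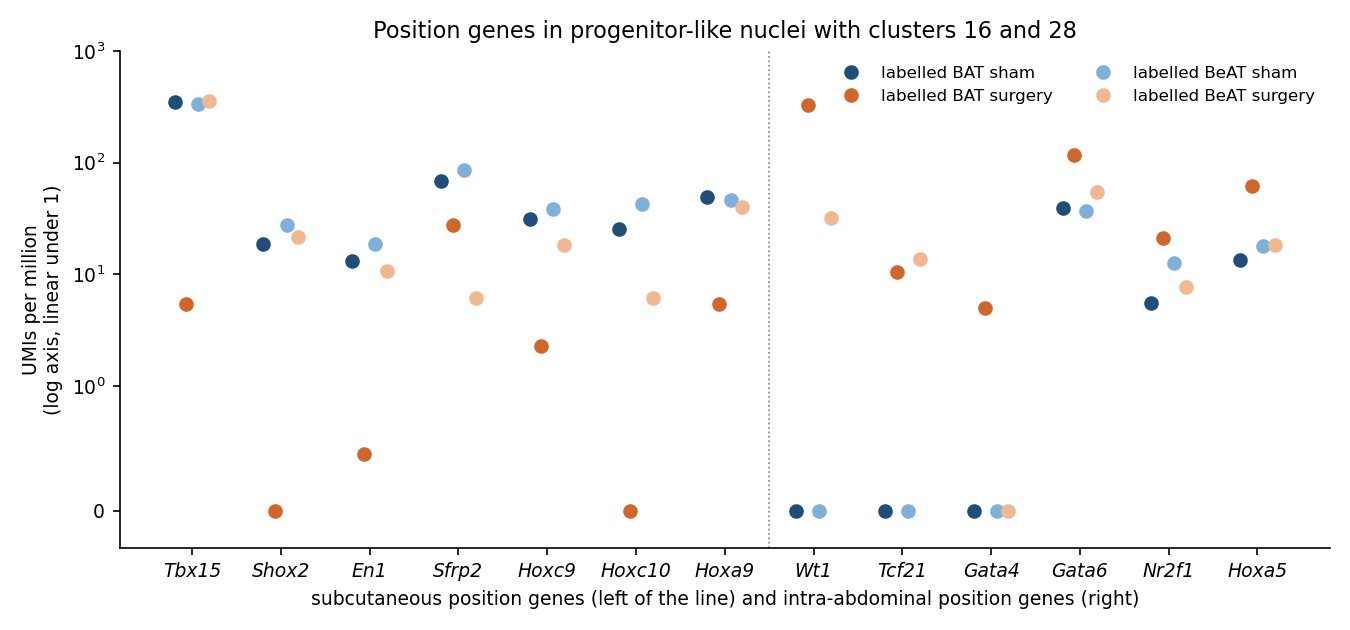
Levels of subcutaneous and intra-abdominal position genes in progenitor-like nuclei with clusters 16 and 28, by labelled library. Genes were chosen after the values were seen.

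Endothelial-like nuclei of both surgery-labelled libraries had lower lipid handling genes than their sham. In BAT the median was −2.12 (−2.36 to −1.63), with 0 higher and 8 lower of 9 genes, with Gpihbp1 (7.96-fold, 6.33 to 10.2), which anchors lipoprotein lipase to the capillary wall, Fabp5 (7.92-fold, 5.64 to 11.5), Fabp4 (7.28-fold, 6.89 to 7.69) and Lpl (4.60-fold, 3.97 to 5.36). In BeAT it was −1.78 (−2.03 to −1.56), with 0 higher and 6 lower of 9 genes, with Gpihbp1 (10.1-fold, 7.67 to 13.4), Fabp5 (61.1-fold, 28.01 to 167), Fabp4 (12.4-fold, 11.6 to 13.2) and the transcription factor gene Tcf15 (5.75-fold, 3.33 to 10.9). With the span trend taken off the medians were −1.34 and −0.92. Cluster 17, which Gpihbp1 leads, held 36.6% of endothelial-like nuclei in BAT sham, 9.34% in BAT surgery, 57.5% in BeAT sham and 6.19% in BeAT surgery. Fabp4 and Lpl are adipocyte genes as well, and the Adipoq levels given earlier show how much adipocyte RNA the sham droplets held. In BAT surgery, endothelial-like nuclei also had the highest of the Gpx5 levels given earlier. How far leaked epithelial RNA lowered the lipid handling genes there was not tested.

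Angiogenesis genes in endothelial-like nuclei stood at −0.35 (−0.61 to −0.02), with 1 higher and 5 lower of 12 genes in BAT, with the receptor genes Kdr (2.08-fold, 1.77 to 2.47) and Aplnr (2.73-fold, 1.78 to 4.37) lower, though the median was 0.02 when nuclei were thinned to 1000 UMIs. How far leaked epithelial RNA lowered these CPM in BAT surgery was not tested. In BeAT they stood at 0.39 (0.07 to 0.59), with 5 higher and 2 lower of 12 genes, and −0.07 without the span trend, with Flt1 (2.44-fold, 2.22 to 2.68) and Efnb2 (2.03-fold, 1.48 to 2.75) higher and Aplnr (3 against 272 UMIs, ratio 0.0712, 0.0146 to 0.210) lower. Of 7983 genes in BAT, 463 were at least 2-fold higher and 1183 lower (1126 and 1425 with no minimum of UMIs, 419 and 685 with the span trend taken off). Of 7152 in BeAT, 1114 were higher and 1623 lower, or 358 and 1222 against BAT sham and 595 and 756 with the span trend taken off. In nuclei of at least 1000 UMIs the BeAT counts were 540 and 1058, and with doublets kept 429 and 849. The top higher genes in BAT, Gpx5 (1400 against 0 UMIs, at least 2077-fold), Lcn8 (297 against 0 UMIs, at least 441-fold), Defb20 (159 against 0 UMIs, at least 236-fold) and Wfdc10 (105 against 0 UMIs, at least 156-fold), are epididymal genes. Scd1 (21.4-fold, 17.4 to 26.5), Dpt (1 against 309 UMIs, ratio 0.0144, 0.000364 to 0.0809), Ifi27l2a (24.1-fold, 12.2 to 56.1) and Cdkn1c (0 against 179 UMIs, at least 13.4-fold) were lower. In BeAT Csmd1 (29.1-fold, 20.5 to 42.3), Pde1c (28.2-fold, 14.4 to 60.1), Esrrg (15.5-fold, 9.57 to 25.8) and Mctp1 (11.0-fold, 9.09 to 13.2) were higher, and Sncg (1 against 624 UMIs, ratio 0.0103, 0.000261 to 0.0578) and Dbi (17.0-fold, 11.6 to 26.1) lower.

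Lipid-associated macrophage genes went opposite ways in the pair of tissue labels. In the library labelled BAT surgery their median was 1.03 (0.69 to 1.59), with 7 higher and 3 lower of 13 genes, with Mmp12 (134 against 0 UMIs, at least 54.9-fold), Gpnmb (7.83-fold, 5.07 to 12.6), Atp6v0d2 (6.96-fold, 5.06 to 9.79) and the tetraspanin gene Cd9 (4.46-fold, 3.29 to 6.15). In BeAT surgery it was −2.08 (−2.40 to −1.97), with 1 higher and 12 lower of 13 genes, with the lipid receptor gene Trem2 (19.5-fold, 7.44 to 72.6), Gpnmb (11.5-fold, 8.14 to 16.9), Atp6v0d2 (6.87-fold, 5.06 to 9.53) and Mmp12 (6.32-fold, 4.397 to 9.38) lower. Without the span trend the medians were 1.55 and −1.87. The size of the BeAT difference depended on the sham library. Between the sham libraries the median was −1.59 (−2.09 to −1.51), with 0 higher and 12 lower of 13 genes, and BeAT surgery against BAT sham gave −0.33, with Gpnmb, Atp6v0d2 and Mmp12 then higher. BAT surgery was not set against BeAT sham. Gpnmb stood at 6.15 CPM in BAT sham, 48.1 in BAT surgery, 399.6 in BeAT sham and 34.6 in BeAT surgery, so both surgery libraries lay between the shams. Resident macrophage genes stood at −0.54 (−0.60 to −0.40), with 1 higher and 4 lower of 11 genes in BAT and −0.15 (−0.54 to −0.09), with 1 higher and 5 lower of 11 genes in BeAT. Selenop (2.63-fold, 2.49 to 2.77), Folr2 (2.37-fold, 2.10 to 2.67) and Cbr2 (2.39-fold, 2.06 to 2.78) were lower in BAT, and in BeAT Selenop (4.64-fold, 4.12 to 5.24) was lower and the phosphatidylserine receptor gene Timd4 (18.3-fold, 13.2 to 26.0) higher.

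Macrophage-like nuclei came from different clusters. Cluster 20, which Saa3, Marco and Timd4 lead, held 1.095% of them in BAT sham, 35.5% in BAT surgery, 19.7% in BeAT sham and 32.4% in BeAT surgery. Cluster 23, which Ccr2 and Lyz1 lead, held 12.1%, 8.15%, 15.8% and 38.5%. Higher in BAT surgery were Saa3 (3112 against 2 UMIs, ratio 1912, 529 to 15797) and Marco (545 against 0 UMIs, at least 223-fold), beside the epididymal genes Defb20 (486 against 0 UMIs, at least 199-fold) and Wfdc10 (254 against 0 UMIs, at least 104-fold). How much of this the share of cluster 20 accounts for was not tested. Retnla (56.2-fold, 46.7 to 68.2), Ccl24 (23.2-fold, 13.9 to 41.8), Pf4 (13.1-fold, 11.0 to 15.8) and Asic2 (55.7-fold, 23.6 to 172) were lower there. In BeAT surgery Colq (451 against 0 UMIs, at least 266-fold), Gpm6b (247-fold, 95.9 to 909), St6galnac3 (134-fold, 78.2 to 253) and Epb41l3 (223 against 2 UMIs, ratio 197, 54.0 to 1639.6) were higher, and the protease gene Ctsl (18.8-fold, 12.5 to 29.5), Ccl8 (10.5-fold, 8.26 to 13.6) and Adra1a (0 against 61 UMIs, at least 11.5-fold) lower. Whether macrophage-like and endothelial-like nuclei of BeAT surgery came from fat or from lymph node tissue was not tested. Of 9774 genes in BAT, 553 were at least 2-fold higher and 662 lower, but 500 and 1195 in nuclei of at least 1000 UMIs and 559 and 1127 when genes were centred within each library before clustering. The split turned to 562 and 484 with the span trend taken off and to 1250 and 1123 with no minimum of UMIs. Of 7058 in BeAT, 602 were higher and 889 lower, or 578 and 482 with the span trend taken off.

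Between the surgery libraries, adipocyte-like nuclei differed more than between the sham libraries, with 437 genes at least 2-fold higher in the library labelled BAT surgery and 339 lower of 9615 (8.07%). With the span trend taken off the numbers were 339 and 396. Immediate early and heat shock genes were far lower in BAT surgery, at −3.41 (−3.77 to −3.13), with 0 higher and 13 lower of 13 genes. Thermogenesis genes stood at −0.76 (−0.92 to −0.43), with 2 higher and 6 lower of 12 genes, and interferon response genes at 0.67 (0.38 to 0.98), with 3 higher and 0 lower of 10 genes. Matrix genes stood at 0.46 (0.31 to 0.60), with 5 higher and 1 lower of 13 genes. The lipogenesis median was −0.16 (−0.20 to −0.11), with 1 higher and 3 lower of 14 genes, the clock median −0.24 (−0.41 to −0.15), with 0 higher and 3 lower of 12 genes, and the gut hormone receptor median 0.01 (−0.09 to 0.06), with 0 higher and 0 lower of 4 genes. The smaller classes gave 115 higher and 185 lower of 2968 genes in progenitor-like, 201 and 116 of 3505 in endothelial-like, and 528 and 482 of 8210 in macrophage-like nuclei. Counting cluster 16 as progenitor-like turned the first split to 854 and 324, and no minimum of UMIs turned the last to 801 and 1211. Between the sham libraries these were 247 and 254 of 10661, 242 and 294 of 9286, and 189 and 273 of 9110. The first became 265 and 98 with the span trend taken off, the second 139 and 493 with median-of-ratios factors, and the last 256 and 218 in nuclei of at least 1000 UMIs.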

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

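Some results stood out, and none of the differences behind them was tested, because each group had 1 library. Immediate early and heat shock genes in adipocyte-like nuclei had opposite medians in the tissue labels, with a log2 ratio of −1.62 for the library labelled BAT surgery against BAT sham and 0.85 for BeAT surgery against BeAT sham. In BAT, Junb, Jun and Egr1 were lower, and in BeAT, Atf3 and Fosb were higher. Lipid-associated macrophage genes in macrophage-like nuclei also went opposite ways, at 1.03 in BAT and −2.08 in BeAT, with Gpnmb and Atp6v0d2 higher in the former and lower in the latter. The sham libraries already differed in these genes. With BAT sham in place of BeAT sham, the BeAT surgery medians kept their signs but became 1.82 for the former list and −0.33 for the latter, while Gpnmb and Atp6v0d2 turned higher.

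A few large clusters that came mostly or only from 1 library took no class name. Cluster 3 held 15.2% of BeAT sham (1485 of its 2183 nuclei), 6.23% of BAT sham and 1.06% of BeAT surgery, and was led by haemoglobin and mitochondrial genes. Cluster 31 took 180 of its 221 nuclei from BeAT sham. In the library labelled BAT surgery, cluster 16 held 5.85% of nuclei (534) and was led by C7, Col6a5 and Wt1. BAT sham, BeAT sham and BeAT surgery gave 108, 56 and 32 more nuclei to it. Cluster 19 held 7.66% of that library, a smooth muscle profile mixed with epithelial RNA. In the library labelled BeAT surgery, cluster 27 held 5.45% (289 of its 340 nuclei) and was led by the cycling and germinal centre genes Mki67, Mybl1 and Rgs13. Cluster 35 held 3.02% of that library and came from no other. These clusters entered no class share.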

How the results depend on the processing

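Results were recomputed under 13 settings fixed in advance and 4 added after the data were examined: span trend taken off, BAT sham in place of BeAT sham, adipocyte cluster 1 only and cluster 16 counted as progenitor-like. Among the lipogenesis and thermogenesis medians of adipocyte-like nuclei, only thermogenesis in BeAT took the other sign. The splits of higher and lower genes between adipocyte-like nuclei of the tissue labels also turned. Between sham libraries, 240 and 154 became 81 and 141 thinned and 59 and 83 at 200 UMIs. Between surgery libraries, 437 and 339 became 362 and 393 with median-of-ratios factors, 339 and 396 without the span trend and 138 and 143 at 200 UMIs. The cause of the shifts was not tested. Shares moved outside their counting interval in 23 of 39 alternatives and list medians in 9 of 44. Counts of genes moved by more than 1.5-fold in 10 of 48, and brown against beige in 11 of 44. The correlation of the tissues left its interval, taken across genes, in 3 of 10. Among the other results, 106 of 401 shares, 167 of 1045 list medians, 44 of 136 gene counts and 47 of 130 brown against beige values moved. Of 1748 values for named genes, 339 moved and 9 turned round. No paired analysis was possible because each group had 1 library and no labels tied libraries to the same animal. Cluster 1 only could not be run for BAT, nor thinning or centring for BAT progenitor-like nuclei, nor centring for BeAT endothelial-like nuclei, since fewer than 50 nuclei were left.

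Shares are in percent. With at least 1000 UMIs, adipocyte-like shares were 45.3 (BAT sham), 56.9 (BeAT sham) and 10.3 (BeAT surgery), T or NK 30.9 and epithelial 64.7. With doublets kept they were 39.6, 47.2 and 8.54, T or NK 25.9, B cell 29.6 and epithelial 60.5. B cell shares were 33.5 at Leiden resolution 0.5 and 35.8 with genes centred. Clustering at 1000 UMIs gave 46.0 (BAT sham), 57.4 (BeAT sham) and 10.7 (BeAT surgery), T or NK 30.8, B cell 29.0 and epithelial 64.9. Outside lymphoid, plasma cell, muscle and epithelial classes adipocyte-like shares were 44.8, 17.5, 51.7 and 24.5.

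Gene counts are for adipocyte-like nuclei. Thinning gave 435 higher and 808 lower in BAT, 1042 lower in BeAT, 81 higher between sham and 112 higher and 109 lower between surgery libraries. A minimum of 200 UMIs gave 372 and 936 in BAT, 290 and 1256 in BeAT, 59 and 83 between sham and 138 and 143 between surgery libraries. With no minimum there were 1396 higher in BAT, 1178 in BeAT, 544 and 303 between sham and 1068 and 799 between surgery libraries. With the span trend taken off, 812 were lower in BeAT.

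Log2 medians moved as follows. Without the span trend, thermogenesis in BAT was −0.59 and lipogenesis in BeAT 0.94. Lipogenesis in BAT was 0.86 thinned, and 0.83 (BAT) and 0.80 (BeAT) with median-of-ratios factors. BeAT surgery against BAT sham gave 0.19 for thermogenesis and 0.92 for lipogenesis, and cluster 1 only 0.54 and 0.83. Pearson r between the tissues was 0.523 thinned, 0.518 without the span trend and 0.647 at 200 UMIs.

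The 9 log2 ratios that turned round were these. Thinned to 1000 UMIs, Cox8b was 0.90 in BAT and Isg15 0.35 in BeAT adipocyte-like nuclei. Creb5 in BAT progenitor-like nuclei was −0.12 with at least 1000 UMIs and −0.94 with cluster 16 in the class. Cidea in BeAT adipocyte-like nuclei was 0.21 against BAT sham and 0.98 in cluster 1 only. In macrophage-like nuclei of BeAT surgery against BAT sham, Atp6v0d2 was 2.04, Gpnmb 2.49 and Mmp12 5.45.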

Other observations

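Genes of the insulin pathway did not all go the same way in adipocyte-like nuclei of the library labelled BAT surgery, and in BeAT surgery this depended on the span trend. Pik3r1, the regulatory subunit gene of PI3-kinase, and Tbc1d4, a substrate of Akt, were higher while Slc2a4, the insulin-responsive glucose transporter gene, was lower: Pik3r1 (6.39-fold, 6.24 to 6.55) and Slc2a4 (2.49-fold, 2.10 to 2.98) in BAT, Pik3r1 (6.36-fold, 6.20 to 6.53) and Slc2a4 (2.13-fold, 1.87 to 2.43) in BeAT. With the span trend taken off, the log2 ratio of Slc2a4 went from −1.32 to −0.83 (−1.09 to −0.58) in BAT and from −1.09 to −0.28 (−0.47 to −0.09) in BeAT, the latter under the 1.5-fold rule for list members. The trend lowers short genes such as this one. Fatty acid synthesis genes were split in the same nuclei, with Acly and Acaca more than 4-fold higher and Fasn under 2-fold, Fasn (1.64-fold, 1.56 to 1.74) and Fasn (1.67-fold, 1.60 to 1.75). Fkbp5 and Cish, target genes of glucocorticoid and of STAT5 signalling, were higher in both pairs. These ratios set 1 library against 1.

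Each of the tests that follow was chosen after the results were seen. The library labelled BAT surgery held 61.6% epithelial-like nuclei, held little Tbx15 and held Wt1. Epididymis in the tissue piece was tested with a list of epididymal genes, and 13 of 13 were at 50 CPM or more in the epithelial-like nuclei, against 1 of 11 mammary genes (Prlr). Values of 10 of those epididymal genes had been seen before the list was written, and of the unseen genes 3 of 3 reached that level, against 0 of 6 unseen mammary genes. Adam7 (6431 CPM), Gpx5 (4863), Spag11b (2419), Lcn5 (1971) and Lcn8 (1939) were the most abundant. Over all kept nuclei of the other libraries, 0 of 13 reached that level, and 1 of 11 mammary genes. That base is not the epithelial-like class, which made up only 0.491% of BAT sham. The count therefore cannot tell what the epithelial-like nuclei of BAT sham are. Fat of an intra-abdominal depot was tested with position genes, and 12 of 12 measured genes went that way in progenitor-like nuclei with clusters 16 and 28, 7 of 7 subcutaneous genes lower and 5 of 5 intra-abdominal genes higher, but cluster 16 is itself led by Wt1 and only 2 of these genes were unseen when the lists were written. Without clusters 16 and 28, 4 of 7 were lower and 2 of 4 higher. Of those 7, Shox2 and En1 were at 0 UMIs in BAT surgery. Their ratio intervals still reached 1.07 and 1.37, so they could not be called lower at this depth. In adipocyte-like nuclei 5 of 6 were lower and 1 of 4 higher. Epithelial RNA in other droplets could replace at most 39.4% of the RNA of that group by the gene that allows most, while Tbx15 stood at 1.57% of its BAT sham level (upper bound 2.74%). Without clusters 16 and 28 leak could replace at most 47.4%, while Tbx15 was at least 24.9-fold lower, so leak is argued against as the reason for the loss of Tbx15. The epithelial-like values are consistent with epididymis in the tissue piece, a hypothesis that records of the dissection could settle. In adipocyte-like nuclei of BeAT surgery, 0 of 6 subcutaneous genes were lower. Hoxa9 and Hoxc10, which the ranking fixed in advance also named, were lower in adipocyte-like nuclei of BAT surgery. The BAT pair therefore differed in position genes. An intra-abdominal depot and a subcutaneous one cannot be told apart, because the position genes were mostly chosen from values already seen. Nor can surgery and a difference in depot be told apart in this pair.

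In the library labelled BeAT surgery, 61.1% of nuclei (59.8 to 62.4) were T or NK, B or plasma cell-like, against 2.37% in BeAT sham. If fewer adipocytes alone had raised the other classes, B cell-like and macrophage-like shares would have gone up by the same factor, but their ratios were 76.2 and 0.787. Lymph node tissue was tested with lists of stroma and germinal centre genes, and 15 of 16 were at 4-fold or more, 8 of 8 in cluster 35 over progenitor-like nuclei and 7 of 8 in cluster 27 over B cell-like nuclei. Most of these genes had been seen before the lists were written, and of the unseen ones 2 of 2 in cluster 35 and 3 of 4 in cluster 27 reached that level, too few to decide. Enpp2 (1550 CPM), Cr2 (692) and Cxcl13 (230) led in cluster 35, and Mybl1 (1142), Bcl6 (412) and Rgs13 (317) in cluster 27, although 4 of these list genes (Enpp2, Bcl6, Fas and Cxcl13) were also found in the sham libraries. The pattern might come from a lymph node in the tissue piece or from surgery, and with 1 library per group these cannot be told apart.

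Lipogenesis and clock genes of adipocyte-like nuclei differed alike in both surgery-labelled libraries. The gene span trend was argued against for lipogenesis, since the lower of the medians was 0.79 (lower bound 0.72) once the trend was taken off, but it fits the respiratory chain in BAT, whose median became 0.0199. Another hour of collection was tested in the other classes with the 13 clock genes listed in advance. A pair of gene and class was called in those classes where its interval excluded 1, with no minimum fold. With the trend taken off, 35 of 38 pairs of gene and class that were called there and in adipocyte-like nuclei of the same tissue went the same way, and 63 of 101 pairs were not called. Without that step it was 47 of 49. Leaked adipocyte RNA in sham droplets could lower the same genes in other classes but could not raise those that were higher in adipocyte-like nuclei. Of pairs whose gene was at least 1.5-fold higher there, 6 went the same way, 0 the other way and 13 of 19 were not called. Arntl was called higher in 6 of 9 pairs, and in 3 of 9 with the trend taken off. Per1 and Per2, higher by less in BeAT, gave 4 pairs the same way and 2 the other way. With the trend taken off, Clock in macrophage-like nuclei was near level, with ratio intervals of 0.970 to 1.18 in BAT and 0.840 to 1.21 in BeAT. Leaked RNA in the surgery droplets, such as the epithelial RNA of BAT surgery, was not weighed for any of these pairs. Another hour of collection and surgery cannot be told apart. Most pairs that adipocyte leak in sham droplets could not raise were not called, and each group had 1 library.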
